A study of Bos taurus with 18 samples.

How the data were processed

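Oocytes were taken from slaughterhouse ovaries, grouped by follicle diameter (under 3 mm, 3 to 5 mm, 5 to 8 mm and over 8 mm) and stripped of cumulus cells, per the labels' protocols. RNA was amplified to antisense RNA and labelled with Cy3 or Cy5 before hybridisation, per the labels. The series lists 3 biological replicates from separate collection weeks for each of 3 larger classes against the smallest class, each with a dye swap, which makes 18 arrays. The scanner files hold each spot's intensity in 2 channels (635 and 532 nm) with its local background, not normalized, per the file headers. The deposited value table holds log2 ratios made by the authors from the same arrays. The steps by which the authors normalized it are not given in the sources used here. Set against the ratios computed here, its columns correlated with r from 0.988 to 1.00, already turned to larger over smallest follicle, with column medians from -0.00344 to 0.00594 and 11 empty cells. Its exact background correction stays unknown.

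Values were computed from the scanner files with limma 3.58.1 in R 4.3.3. Spot means were corrected for median background with normexp (offset 50) and normalized within each array by loess, with control and flagged spots given no weight. The choice of spot means over spot medians was not fixed in advance. Flagged spots (4 to 58 per array) were set missing and 14 summary lines per file were left out. A probe was kept where its mean log2 intensity over all arrays lay above the 95th percentile of 153 negative control spots, which left 36177 of 43794 probes (82.6%). Between 62.4% and 84.6% of probes on an array lay above the negative controls of the same channel. Ratios within an array cannot show a change in total messenger RNA per oocyte.

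The labels do not say which forward and swapped arrays share RNA extracts. Within each class the 3 forward arrays were matched with the 3 swapped arrays by the highest summed correlation of their deviations from the mean of their class and dye, a rule fixed before the data were examined. The 9 pairs so formed correlated with r from 0.759 to 0.889, and other combinations at -0.271 or below. Centring on 3 arrays forces part of the negative values, which are no separate support for the pairing. In simulated arrays that shared a part within each pair, sized from the spread under this pairing, the rule recovered 150 of 150 pairings. Each pair was averaged, so that dye effects cancel, and counted as 1 replicate.

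One linear model with a mean for each larger class was fitted to the 9 pair means with lmFit and eBayes, so that the classes share 1 estimate of spread with 6 residual degrees of freedom. Each class was tested against 0, each pair of classes against each other, and a linear trend was tested with the smallest class at 0. Benjamini-Hochberg adjustment ran over the detected probes, with a threshold of 0.05. P-values and standard errors rest on this shared spread of pair means about their class means, as moderated by eBayes. They do not measure the spread of a class's own 3 pair means. The larger classes were never on the same array. Whether the reference pools of different arrays were the same extracts is not labelled; reference oocytes enter each ratio, so their own spread is part of the error only as far as their pools differ. The direction of each ratio follows the dyes in the labels. For 22 gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01 and with an estimated correlation. Slides and scan batches were unevenly spread: slides of the over 8 mm class held no other class, and the first scan batch held 2 arrays, both of 5 to 8 mm.

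Gene names came from the platform annotation, in which 21790 probes had 1 symbol, 0 had several and 22004 had none. Of those with a symbol, 20025 were current in the ARS-UCD2.0 gene table, 1524 were synonyms of 1 current symbol and 241 had no match, so some names are old. The sources name no coordinates for the probes, and none are given. Each gene was represented by its brightest detected probe. Named genes were, per comparison, the 12 largest rises and 12 largest falls past the threshold with the same sign in all pairs (or at every step, for the trend), filled up to 5 by smallest p where fewer passed, with up to 4 members of each list with the smallest p, 10 genes always named, and the 5 largest rises and falls between larger classes. Genes that filled up a direction also had an absolute log2 fold of at least 0.58. Only part of the named genes are printed. There were 466 named results, and background and saturation were counted only for those against under 3 mm. Of those, 0 had a side at background on all 6 arrays and 0 had a side saturated on all 6. No fold against under 3 mm therefore had to be given as a bound. Named results for the trend and between larger classes were not checked in this way.

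The model was tested on simulated pair means drawn with the observed spread of each of 35862 probes. With 200 changed probes at 5 to 8 mm it recovered 38.8%, 89.6% and 100% of changes of 0.5, 1 and 2 on the log2 scale, with 8 false calls among 160. The shares were 31.3%, 77.6% and 98.5% at 3 to 5 mm, 40.3%, 86.6% and 98.5% over 8 mm and 32.8%, 83.6% and 98.5% for the trend. Between classes they were 7.46%, 62.7% and 95.5% for 5 to 8 mm against 3 to 5 mm, 11.9%, 64.2% and 93.9% for over 8 mm against 5 to 8 mm, and 4.48%, 58.2% and 93.9% for over 8 mm against 3 to 5 mm. Pair means were drawn independently, although the real ones were linked across classes (r from 0.320 to 0.556). The shares between classes and for the trend thus hold for unlinked pair means only. Errors were also drawn independently between probes, so the simulated lists test no correlation between genes. Of these lists camera found 0 of 20, 20 of 20 and 20 of 20 at shifts of 0, 0.1 and 0.3. Alternatives fixed with the design covered background correction, normalization, the dim-probe filter, the authors' table, pairing, slide, separate fits, weights, the prior, a fold minimum and leaving out each pair. Added later were spot medians, a brighter filter, blocks of linked replicates and leaving out the first scan batch. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.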

Results

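The series measured messenger RNA in cattle oocytes grouped by the diameter of the follicle they came from. Oocytes were freed of cumulus cells, and their amplified RNA was hybridised to 18 arrays with 2 dyes. Each array set oocytes from 1 of 3 larger follicle classes (3 to 5 mm, 5 to 8 mm and over 8 mm) against oocytes from follicles under 3 mm. Each larger class had 6 arrays, 3 in each dye orientation, which were averaged into 3 dye-swap pairs, so that n = 3 throughout. Every ratio is given as larger over smallest follicle. Median raw spot intensity per array ran from 101 to 194 in Cy5 and from 102 to 228 in Cy3, and 36177 of 43794 probes lay above the negative control spots on average. With 3 pairs per class, the number of pairs limits the precision of every fold. Each SE given below comes from the spread shared by the 3 classes, not from the class's own 3 pairs. Array ratios are relative to the other transcripts of the same oocytes, so a change in total RNA per oocyte would not be seen.

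Oocytes from follicles of 3 to 5 mm, the smallest of the 3 larger classes, were compared with those under 3 mm. No gene passed the threshold. Genes were then ranked by p among those with an absolute log2 fold of at least 0.58 and the same sign in the 3 pairs. The smallest p on the higher side included CKS1B, a cyclin-dependent kinase partner, at 0.74 ± 0.12 on the log2 scale (SE, n = 3 pairs). CETN3, a centrosome protein, was at 0.77 ± 0.14, and GML at 0.89 ± 0.17. On the lower side stood TMED9 and TMED1, cargo receptors of the early secretory pathway, at -0.62 ± 0.08 and -0.68 ± 0.09, DCAF8 at -0.78 ± 0.14, and CPEB4, an RNA-binding protein of the polyadenylation machinery, at -0.74 ± 0.14. TMED1 and CPEB4 each had another detected probe of the opposite sign. All of these genes had the same sign in the 3 pairs and an adjusted p of 0.492 in limma with Benjamini-Hochberg adjustment. Among oocyte genes, none of which passed, the germ cell RNA-binding protein gene DAZL was at 1.30 ± 0.46 (adjusted p = 0.62). OOSP1 (now named OOSP2) was at 0.76 ± 0.25, H1FOO at -0.52 ± 0.36, the zona pellucida gene ZP3 at -0.32 ± 0.12, and the growth factor genes GDF9 and BMP15 were at -0.16 ± 0.11 and -0.14 ± 0.10. In limma 0 probes had an adjusted p under 0.05, against 2531 with an unadjusted p under 0.05, and 0 of the 22 gene lists shifted (smallest camera adjusted p 0.219, for maternal mRNA storage and decay). Without the 3 to 5 mm pair numbered 1 that list passed (0.000365). So did DNA methylation and histone modifiers (0.0254), cytosolic ribosomal proteins (0.0254) and oxidative phosphorylation (0.0406). With median centring oxidative phosphorylation (0.024) and splicing factors (0.0253) passed. In simulated data with 200 changed probes, 77.6% of the changes of 1 on the log2 scale and 31.3% of those of 0.5 were recovered for this comparison. Treating the 18 arrays as separate samples, which counts each dye swap as a replicate, gave 869 probes.

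Follicles of 5 to 8 mm gave the most changed probes. The largest falls were in the transcription factor gene FOXP4 at -2.20 ± 0.32 (SE, n = 3 pairs), DGAT2, the enzyme of the last step of triacylglycerol synthesis, at -2.11 ± 0.30, the cell surface glycoprotein gene BSG at -2.09 ± 0.24, and the transcription elongation factor gene SUPT6H at -1.96 ± 0.30. They were followed by TMBIM6 at -1.89 ± 0.34, DHPS, which makes hypusine, at -1.84 ± 0.22, the laminin gene LAMA1 at -1.83 ± 0.43, CPSF1 of the mRNA cleavage and polyadenylation complex at -1.73 ± 0.22, the N-glycan enzyme gene MGAT1 at -1.71 ± 0.20 and the importin gene IPO13 at -1.69 ± 0.18. The largest rises were in SLC25A16 at 1.75 ± 0.39, LEPROT at 1.63 ± 0.25, SLC25A31, a mitochondrial ADP/ATP carrier, at 1.57 ± 0.34, TMPO, a nuclear envelope protein, at 1.55 ± 0.20, TEX12 of the synaptonemal complex at 1.54 ± 0.36 and ELF1, an ETS-family transcription factor, which rose 2.84-fold. Further rises lay between 1.37 and 1.44 on the log2 scale. They were in TMEFF1, the protein phosphatase subunit gene PPP1CB, the mRNA export factor gene THOC7 and the SUMO-activating enzyme gene UBA2. TYW1 and LGR4, a receptor for R-spondins, lay in the same range. Adjusted p in limma for the genes named so far in this class ran from 0.00211 for THOC7 to 0.0288 for LAMA1. In all, 2401 probes were higher and 2700 lower of 36177, or 970 and 1429 of 13377 genes. The count fell to 2094 probes with this class fitted alone, and to 2044, 3002 and 1718 without the pairs numbered 1, 2 and 3. Without the 2 pairs that hold an array scanned apart from the rest it was 3, with 1 pair left in this class.

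**Figure D1:**
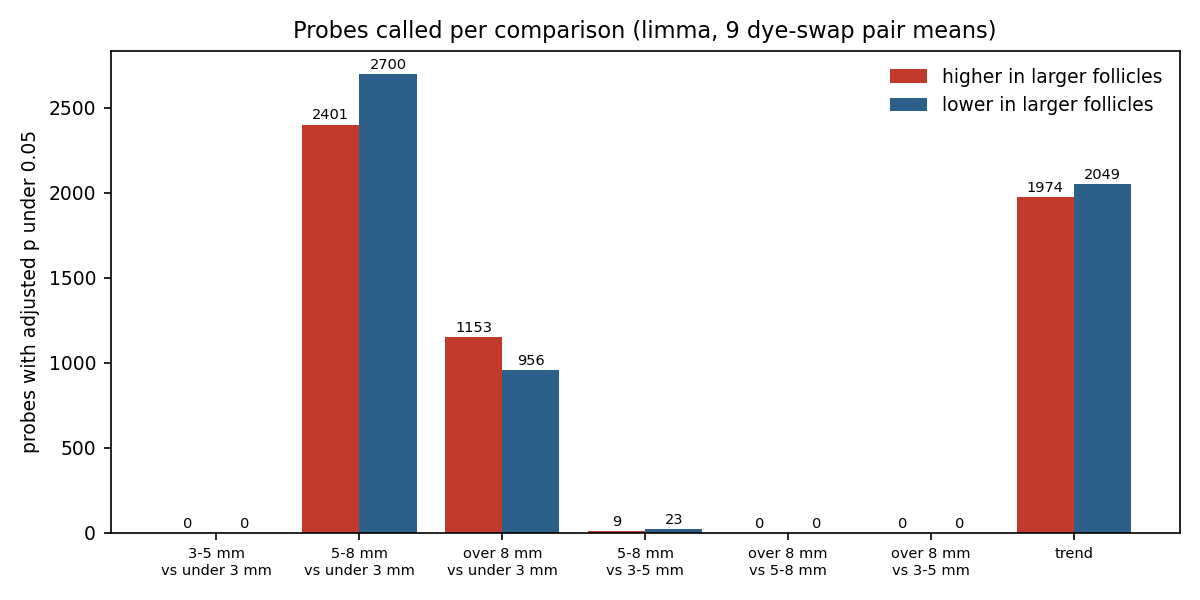
Probes with a limma adjusted p under 0.05 in each comparison, split into higher and lower in the larger follicles, on a linear axis that starts at 0. The bars are tallest for 5 to 8 mm against under 3 mm, with 2401 higher and 2700 lower, and are at 0 for 3 to 5 mm.

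Among genes expressed mainly in the oocyte, several fell at 5 to 8 mm. NLRP5, a maternal effect gene of the oocyte cortex, was at -1.70 ± 0.15 (SE, n = 3 pairs), and the zona pellucida genes ZP3 and ZP4 were at -1.22 ± 0.12 and -0.84 ± 0.09. ASTL, an oocyte protease that acts on the zona at fertilisation, was at -1.18 ± 0.15. Adjusted p in limma was 0.00193, 0.00228, 0.00299 and 0.00433 in that order. Of 35 measured members of the oocyte and zona list, 8 were lower, 2 higher and the others not past the threshold, against 10 lower and 3 higher when adjusted over the list alone. The 2 higher genes, FBXO43 at 0.81 ± 0.16 and OOSP1 (now named OOSP2) at 0.92 ± 0.25, were picked out after their values were seen. GDF9 at -0.27 ± 0.11, BMP15 at -0.10 ± 0.10, DPPA3 at 0.35 ± 0.13 and H1FOO at -0.89 ± 0.36 did not pass, with adjusted p of 0.149, 0.638, 0.119 and 0.151. As a whole this list did not shift against the other genes (camera adjusted p = 0.251, and 0.702 with an estimated correlation).

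**Figure D2:**
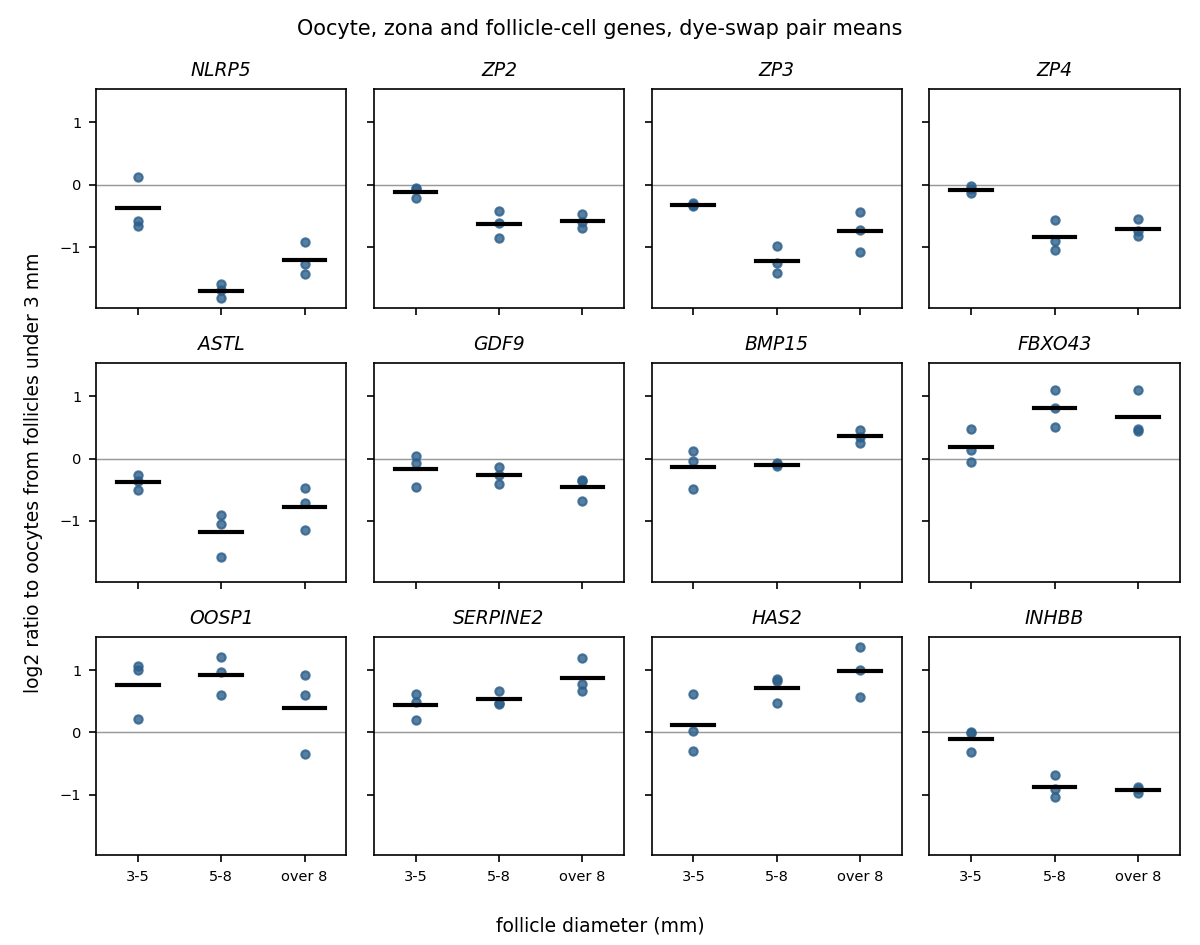
Log2 ratio to oocytes from follicles under 3 mm, on a shared linear axis, for 12 oocyte, zona and follicle-cell genes in the 3 larger follicle classes. Points are the 3 dye-swap pair means of a class and short lines their mean; NLRP5 averaged -1.70 at 5 to 8 mm and -1.20 over 8 mm.

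Of 22 measured glycolysis and pentose phosphate genes, 7 were lower at 5 to 8 mm, 0 higher and 15 not past the threshold. Enolase (ENO1) was at -0.84 ± 0.06 (SE, n = 3 pairs, limma adjusted p = 0.00146), triosephosphate isomerase (TPI1) at -1.33 ± 0.19, glucose phosphate isomerase (GPI) at -0.89 ± 0.15 and phosphogluconate dehydrogenase (PGD) at -0.50 ± 0.07. ENO1 had another detected probe with the opposite sign. Adjusted over the list alone the count was also 7 lower. The list as a whole had a camera adjusted p of 0.0514, just outside the threshold, and 0.429 with an estimated correlation. It passed without the 5 to 8 mm pairs numbered 1 and 3 (0.0463 and 0.0211) and with dim probes kept (0.0175). It also passed without the 3 to 5 mm pairs numbered 1 (0.0445) and 3 (just under 0.05). Of 82 measured subunits of oxidative phosphorylation, 21 were lower and 10 higher (15 higher and 27 lower adjusted over the list alone), and the list did not shift (camera adjusted p = 0.485). The list of M-phase regulators went both ways, with 12 of 71 higher and 8 lower (17 and 13 adjusted over the list alone): the kinesin gene KIF2C was at -1.10 ± 0.09, CDC20, an activator of the anaphase-promoting complex, at -1.30 ± 0.16, CKS1B at 1.07 ± 0.12 and FBXO5, an inhibitor of that complex, at 1.32 ± 0.20. Markers of cells other than the oocyte were also among the genes called, which over all 13377 genes were 970 higher and 1429 lower. The share called was below that over all genes for theca and stroma markers and for blood, immune and endothelial markers. No marker list shifted (camera adjusted p = 0.968 for cumulus and granulosa, 0.989 for theca and stroma, 0.485 for blood, immune and endothelial). Of 36 measured cumulus and granulosa markers 6 were higher and 2 lower. The higher ones were PTX3 at 0.49 ± 0.07, FDX1 at 0.38 ± 0.05, PTGS2 at 0.86, HAS2 at 0.71, PRSS35 at 0.66 and SERPINE2 at 0.53. The lower ones were INHBB at -0.88 ± 0.09 and INHBA at -1.25 ± 0.23, which encode activin subunits. Of 15 theca and stroma markers 1, CNN1, was lower at -0.86 ± 0.18, and of 22 blood, immune and endothelial markers 1, CD3E, at -0.41 ± 0.09.

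Oocytes from follicles over 8 mm showed a drop in DGAT2 of 9.54-fold, at -3.25 ± 0.30 on the log2 scale (SE, n = 3 pairs, limma adjusted p = 0.00548). IPO13, TMBIM6, NLRP5 and MGAT1 again lay among the largest falls, at -1.31 ± 0.18, -1.46 ± 0.34, -1.20 ± 0.15 and -1.20 ± 0.20, together with REEP4 at -1.35 ± 0.22, the neutral amino acid transporter gene SLC1A4 at -1.27 ± 0.16, MANSC1 at -1.26 ± 0.09 and the ribosomal S6 kinase gene RPS6KA1 at -1.23 ± 0.28. The largest rises were in TMPO at 1.80 ± 0.20, ELF1 at 1.78 ± 0.18, PPP1CB at 1.46 ± 0.24, LMBRD2 at 1.46 ± 0.15 and PRRC1 at 1.42 ± 0.23. GMPPA, MORC3, PPFIA1, TYW1, LGR4, DTWD2 and the deoxycytidine kinase gene DCK rose by between 1.26 and 1.40 on the log2 scale. However, another detected probe of GMPPA had the opposite sign. In all, 1153 probes were higher and 956 lower, or 477 and 496 genes. With median centring 948 of 2057 were higher, so neither direction prevailed. The count depends on the model of the spread: 0 probes passed with this class fitted alone, and 0 in limma with a trended and robust prior, against 8381 with an unadjusted p under 0.05. Without the pairs numbered 1, 2 and 3 of this class the count was 132, 128 and 947.

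Over 8 mm, 7 of the 35 oocyte and zona genes were lower and 0 higher (9 lower and 4 higher adjusted over the list alone). ZP4 was at -0.70 ± 0.09, ZP2 at -0.58 ± 0.09 and ZP3 at -0.74 ± 0.12 (SE, n = 3 pairs), although another detected ZP2 probe had the opposite sign. GDF9 was at -0.46 ± 0.11 with a limma adjusted p of 0.0502, and BMP15 at 0.36 ± 0.10 with 0.0845. Splicing factors were the list that shifted against the other genes (camera adjusted p = 0.035), a shift lost with an estimated correlation (adjusted p = 0.411). Of 68 measured members 9 were higher and 2 lower, led by the splice site recognition factor gene U2AF1 at 0.82 ± 0.07, HNRNPH1 at 0.58 ± 0.07 and SF3B14 at 0.76 ± 0.12, and 16 were higher and 5 lower adjusted over the list alone. HNRNPH1 had another detected probe with the opposite sign. That shift was also lost with median centring of the arrays (0.0506) and without the pair numbered 3 of this class (0.0908). Among the list of gap junction and follicle signalling genes, 6 of 49 were higher and 1 lower (9 and 2 adjusted over the list alone), with the bone morphogenetic protein receptor genes BMPR2 and BMPR1A at 1.09 ± 0.16 and 0.75 ± 0.13 and the TGF-beta receptor gene TGFBR1 at 0.83 ± 0.17. Of the 36 cumulus and granulosa markers 4 were higher: SERPINE2 at 0.87 ± 0.11, the cyclooxygenase gene PTGS2 at 0.96 ± 0.17, the hyaluronan synthase gene HAS2 at 0.98 ± 0.19, and GJA1, picked out after its value was seen, at 0.84 ± 0.19. INHBB was lower at -0.92 ± 0.09, and the steroidogenic genes STAR and CYP19A1 were at -0.00 ± 0.13 and 0.06 ± 0.05. Of the theca and stroma markers 0 passed in limma, and 2 of the 22 blood, immune and endothelial markers were lower, CSF1R at -0.82 ± 0.09 and CD3D at -0.51 ± 0.10.

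At 5 to 8 mm, 12 of the 68 splicing factors were higher and 7 lower (camera adjusted p = 0.0984, and 0.487 with an estimated correlation). With median centring that list passed at 5 to 8 mm (0.0379). Over 8 mm, 3 of the 22 glycolysis and pentose phosphate genes were lower and 0 higher (camera adjusted p = 0.114). Without the pair numbered 1 over 8 mm that list passed (0.0489). None of the other gene lists shifted as a whole against under 3 mm (camera adjusted p of 0.118 or more). Some passed with 1 pair left out. Over 8 mm, cytosolic ribosomal proteins and oxidative phosphorylation did so without the pair numbered 3 (0.00689 for each). Histone genes, maternal mRNA and M-phase regulators did so there without the pair numbered 1 (0.0489 for each). At 5 to 8 mm histone genes passed without the pair numbered 1 (0.0463). Among 17 histone genes 3 were higher and 0 lower at 5 to 8 mm, with the histone variant gene H2AFV at 1.03 ± 0.10 and H3F3C at 0.86 ± 0.12 (SE, n = 3 pairs), and 2 were higher over 8 mm. Of 20 histone mRNA processing and chaperone genes 2 were higher and 3 lower at 5 to 8 mm, with the FACT subunit gene SUPT16H at -1.22 ± 0.12 and over 8 mm 1 was higher, CASP8AP2 at 1.07 ± 0.21, and 2 lower. Among 29 meiotic prophase and cohesin genes 6 were higher and 4 lower at 5 to 8 mm. The cohesin gene RAD21 was at 0.90 ± 0.17 there and 1.12 ± 0.17 over 8 mm, where 2 were higher and 0 lower, and STAG3 was at -0.69 ± 0.09 at 5 to 8 mm. Of 53 genes of maternal mRNA storage, polyadenylation and decay 7 were higher and 10 lower at 5 to 8 mm and 4 higher and 3 lower over 8 mm, including the deadenylase gene CNOT6 at 0.75 ± 0.14 over 8 mm. Adjusted over the list alone, 13 of these were higher and 7 lower over 8 mm. Of 60 DNA methylation and histone modifier genes 5 were higher and 11 lower at 5 to 8 mm, with SIRT2 at -1.23 ± 0.22, and 1 higher and 0 lower over 8 mm. Of 33 fatty acid oxidation and lipid droplet genes 1 was higher and 6 lower at 5 to 8 mm and 4 lower over 8 mm, among them the lipid droplet coat gene PLIN3 at -0.80 ± 0.17 and -0.85 ± 0.17. The counts higher and lower at 5 to 8 mm were 7 and 6 of 66 cytosolic ribosomal proteins, 14 and 9 of 76 mitochondrial ones, 4 and 5 of 37 proteasome subunits and 6 and 6 of 45 nucleolar genes. They were 6 and 6 of 32 antioxidant genes, with PRDX2 at -1.07 ± 0.12 and SEPP1 at 0.91 ± 0.16. They were 4 and 2 of 34 unfolded protein and heat shock genes, with CALR at -1.10 ± 0.15 and DNAJB11 at 0.66 ± 0.06, and 2 and 1 of 28 apoptosis regulators, with APAF1 at 0.91 ± 0.15. Over 8 mm they were 3 and 1, 2 and 3, 2 and 2, 2 and 4, 2 and 1, 4 and 0 and 2 and 1 in the same order, with p from limma. Adjusted over the list alone, the counts higher and lower at 5 to 8 mm were 5 and 0 for histones, 5 and 5 for histone processing, 8 and 4 for prophase and cohesin. They were 10 and 12 for maternal mRNA, 7 and 14 for methylation and modifiers and 3 and 9 for fatty acid genes. They were 10 and 12 for cytosolic and 19 and 12 for mitochondrial ribosomal proteins, 8 and 5 for the proteasome, 10 and 7 for nucleolar, 8 and 7 for antioxidant, 5 and 2 for unfolded protein and 2 and 1 for apoptosis genes.

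The 2 largest classes were set side by side through their common reference. Of the probes called, 824 were higher and 754 lower in both, and 3 went opposite ways, against 76.5 and 71.3 for independent lists. The log2 folds of the classes correlated across probes with r = 0.776, where unchanged groups against shared reference oocytes gave 0.497 in simulation; the covariance was 0.0777 against a simulated 0.00946. Probes are not independent replicates, and the reference could not be split, so part of the overlap may come from it. A direct contrast of over 8 mm with 5 to 8 mm found 0 probes in limma (2306 with an unadjusted p under 0.05), and over 8 mm with 3 to 5 mm also 0 (3569 with an unadjusted p under 0.05). A block of replicates linked across classes, inferred from correlations and chosen after the data were seen, gave 274 probes (fixed) or 92 (random) for over 8 mm against 3 to 5 mm, and 0 or 1 against 5 to 8 mm. Follicles of 5 to 8 mm differed from those of 3 to 5 mm in 32 probes, 9 higher and 23 lower (1888 or 1008 with that block). The named genes among them were CIAPIN1, a factor in iron-sulphur cluster assembly, at -1.46 ± 0.18 (SE), AMICA1 at -1.44 ± 0.15, the mitochondrial peptidase gene PITRM1 at -1.34 ± 0.16, GRHPR at -1.16 ± 0.10, the spliceosome core gene PRPF8 at -1.15 ± 0.13 and RBM18 at 0.83 ± 0.10, with limma adjusted p from 0.0277 to 0.0481. Median centring gave 7 probes, 0 of them higher. Without 1 pair at a time the count of 32 fell to between 0 and 20. Without the 3 to 5 mm pair numbered 1, 13 of the 20 were higher, and without any of the other 5 pairs 0 probes passed in limma.

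A linear trend over the 4 ordered classes was fitted to ask whether transcripts build up or decline gradually with follicle size. DGAT2 declined by -1.16 ± 0.10 per class on the log2 scale (SE), REEP4 by -0.51 ± 0.07, SLC1A4 by -0.46 ± 0.05, the branched-chain keto acid dehydrogenase gene BCKDHA by -0.37 ± 0.06, the kinase gene AKT2 by -0.39 ± 0.08 and INHBB by -0.35 ± 0.03. TMPO gained 0.66 ± 0.07 per class, ELF1 0.61 ± 0.06, PPP1CB 0.54 ± 0.08, LMBRD2 0.51 ± 0.05, DCK 0.47 ± 0.05 and the nuclear matrix gene MATR3 0.47 ± 0.04. These genes changed in the same direction at each step, which was the rule for naming the largest trends and so is no separate result. Their limma adjusted p ran from 0.00182 for INHBB to 0.0187 for AKT2. INHBB fell little at the last step, from -0.88 at 5 to 8 mm to -0.92 over 8 mm. GMPPA also gained 0.53 ± 0.06, although its other detected probe had the opposite sign. ZP3 and NLRP5 had slopes of -0.31 ± 0.04 and -0.49 ± 0.05 but lay lower at 5 to 8 mm than over 8 mm. In all, 1974 probes rose and 2049 fell with size. Of these, 1179, or 29.3%, had class means that moved one way at every step, against 11.5% of all probes. A trend call itself makes such steps likelier, so these 2 shares are no test. Of 100 assignments of the pair means to the classes, the real one included, 6 gave at least as many such calls. Splicing factors shifted upward (camera adjusted p = 0.0389, 13 higher and 3 lower of 68) and glycolysis and pentose phosphate genes downward (0.0389, 5 lower and 0 higher of 22), and both shifts were lost with an estimated correlation (adjusted p = 0.289 for each). Adjusted over the list alone, 17 splicing factors were higher and 4 lower, and 8 glycolysis genes were lower and 1 higher. The splicing shift also lay outside the threshold without the pairs numbered 2 or 3 over 8 mm, 2 at 5 to 8 mm or 3 at 3 to 5 mm (0.0581, 0.0935, 0.0516 and 0.0526). The glycolysis shift did so without the pairs numbered 2 over 8 mm, 2 at 5 to 8 mm or 2 or 3 at 3 to 5 mm (0.0953, 0.0516, 0.0543 and 0.0526), and with the mean of all probes of a gene (0.0503). Without the pairs numbered 1, 2 and 3 of the over 8 mm class the trend count was 1207, 1949 and 2602, and it was 2433 with a trended and robust prior.

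**Figure D3:**
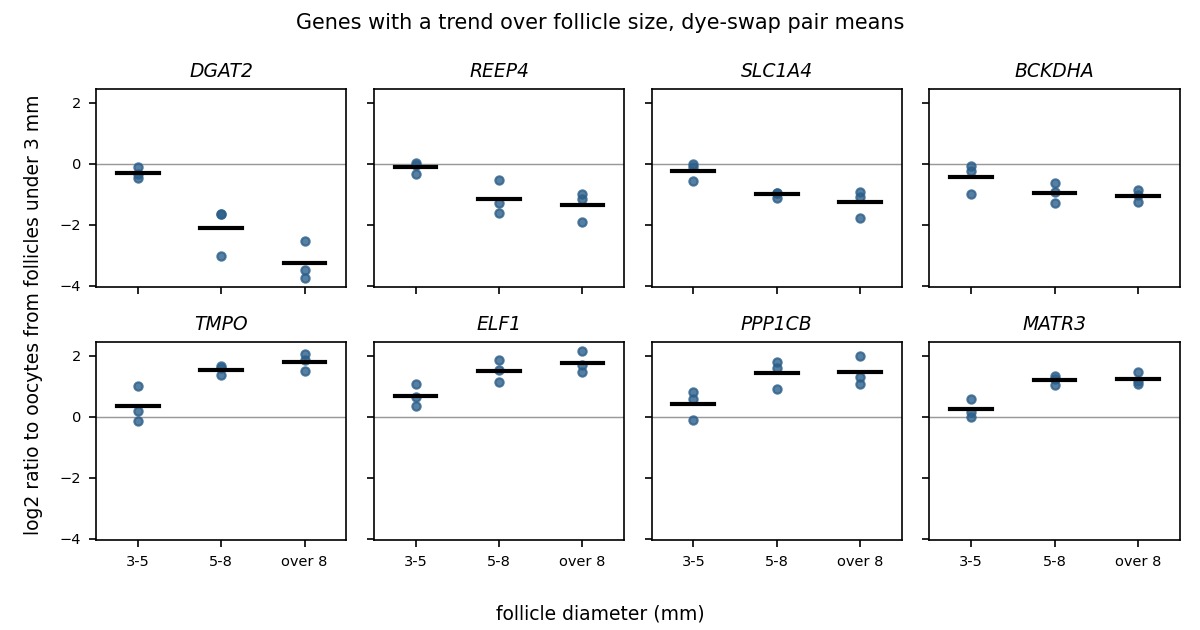
Log2 ratio to oocytes from follicles under 3 mm, on a shared linear axis, for 8 genes with a trend over follicle size. Points are the 3 dye-swap pair means of a class and short lines their mean; DGAT2 averaged -0.31, -2.11 and -3.25 and TMPO 0.36, 1.55 and 1.80 from 3 to 5 mm to over 8 mm.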

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

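The tests on shared reference oocytes and carried-over cumulus cells below were chosen after the results were seen; the tests on gene length and the scan were written before theirs. Tests of signal strength, which loess had already removed, and of blood or stroma carry-over were dropped before being run. Each count of calls was also set against other groupings of the same pair means.

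In 6 measures per array over 3 classes, 18 sets of 6 arrays were searched for an array apart from the rest, of which chance marks about 1 in 20. In 3 sets an array stood apart. An over 8 mm array had the lowest median intensity of its class in both channels, at 113 in Cy5 and 153 in Cy3, and a 3 to 5 mm array had the highest Cy3 median of its class, at 228. Pair means were not searched, since a class has 3.

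The 5 to 8 mm and 3 to 5 mm effects differed in 32 probes by a test of the difference itself. The log2 difference was 0.83 for RBM18, -1.15 for PRPF8, -1.16 for GRHPR, -1.34 for PITRM1, -1.44 for AMICA1 and -1.46 for CIAPIN1. The real split of the 6 pair means gave 32 probes and the highest of the others 0; with 10 splits in all, 1 as large cannot give a share under 0.05.

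Many genes changed in follicles of 5 to 8 mm and over 8 mm. Risers were longer genes: the median genomic span was 36.5 kb for genes higher over 8 mm and 16.1 kb for genes lower, with a Spearman rho across genes of 0.159. Taking a trend on span out of each pair mean left at least 94.4% of the gene calls of each class past the threshold with the same sign. This argues against genomic span as the whole cause. With rho this low few calls could be lost, and transcript length was not measured. Chance deviations of shared reference oocytes would appear at 3 to 5 mm as well, yet the 1578 probes called the same way in both classes had a median fold there of 24.6% of that in the called classes (highest pair 41.8%). Of these probes 86.2% had the same sign there, so a smaller share of the folds from the shared reference, or early change, is not excluded. Simulated unchanged groups with a shared reference gave the same sign as 3 to 5 mm in 66.9% (5 to 8 mm) and 66.8% (over 8 mm) of probes. That simulation took all probes and not those picked by calls. Follicle size, the difference the design names, and the amplification of RNA stay open and were not separated by any test here.

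Folds were larger at 5 to 8 mm than over 8 mm (SD of 0.35 against 0.286 over all probes), although no probe differed between the classes in limma. The first scan batch holds 2 arrays of the 5 to 8 mm class, with the lowest Cy3 medians of the 18. Over the probes called over 8 mm, the pair with no such array had a median fold of 0.548 in the direction of the calls, or 88.1% of the mean of the other pairs (0.611 and 0.631), which lies between the bounds set beforehand. With 1 pair free of the batch, scan and replicate cannot be told apart.

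Cumulus genes HAS2, PTGS2, SERPINE2 and GJA1 were higher over 8 mm. The first 3 were already higher past the threshold at 5 to 8 mm, at 0.71, 0.86 and 0.53. GJA1 was at 0.63 there (limma adjusted p = 0.0584), and INHBA and INHBB were lower. The test below was made over 8 mm only. Of 13 cumulus and granulosa markers with a mean log2 intensity of 8 or more, 8, or 61.5%, lay above 0, with 4 higher and 1, INHBB, lower past the threshold. The brightest, STAR, was at -0.00. The bounds of this test were changed after its values had been seen: under the earlier bounds the 61.5% and the lower INHBB would have spoken against carried-over cumulus cells, and under the later, wider ones the test decides nothing. How much of each marker's signal the oocyte itself gives is unknown, so carry-over, which may persist after stripping, and expression in the oocyte cannot be told apart (61.5% above 0).

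For each larger class against under 3 mm, the 3 pair means have 4 sign patterns, too few for a share under 0.05. At 5 to 8 mm the real count was 5101 and the highest other 0, with 1 of the 4 as large. Over 8 mm the real count was 2109 and the highest other 0, with 1 as large. At 3 to 5 mm all 4 gave 0. The contrasts of over 8 mm with 5 to 8 mm and with 3 to 5 mm gave 0 in each of their 10 splits. For the trend, 3 of 100 assignments of the 9 pair means to the classes gave at least the real 4023 probes, the real one included, and the highest other gave 4596. That share lay under the bound of 0.05 set beforehand. The other assignments were drawn at random and mixed pair means freely, although these were linked across classes (r from 0.320 to 0.556). A share this near the bound in such a draw does not exclude a chance order of the pair means. For calls that moved one way at every step, 6 of 100 assignments gave at least the real 1179, and the highest other gave 2527. A chance order is not excluded there either. The median over the drawn assignments was 0 for both of these counts.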

How the results depend on the processing

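Each count below stands against 5101 probes at 5 to 8 mm, 2109 over 8 mm, 4023 for the trend, 32 for 5 to 8 mm against 3 to 5 mm, 3 list shifts, and 0 in limma at 3 to 5 mm (2531 at an unadjusted p under 0.05), for over 8 mm against 5 to 8 mm (2306) and against 3 to 5 mm (3569). No named gene or list past the threshold in either fit turned its direction under an alternative in which it was refitted. Passing the threshold was less stable. With 1 pair left out, 456 named-gene values no longer passed and 4 newly passed, against 1670 with the same call. Among list results 9 were lost and 18 gained, against 765 with the same call. Named genes were not refitted with each class alone or with a trended and robust prior, where 0 probes passed over 8 mm. The balance of higher and lower calls did turn. Over 8 mm, 1153 of 2109 were higher, against 948 of 2057 with median centring, 4322 of 8718 with the 18 arrays as separate samples and 5160 of 10503 with slide as a block. For the trend, 1974 of 4023 were higher, against for example 1247 of 2433 with a trended and robust prior and 1697 of 3170 with spot medians, so neither direction prevailed. For 5 to 8 mm against 3 to 5 mm, 9 of 32 were higher, against 13 of 20 without the 3 to 5 mm pair numbered 1. Signal limits dim probes, and 3 pairs per class limit every count. Except where said, the cause of a difference was not tested.

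With the 18 arrays as separate samples, which counts a dye swap as a replicate, the counts were 869 at 3 to 5 mm, 11360 at 5 to 8 mm, 8718 over 8 mm, 10655 for the trend, 3537 for 5 to 8 mm against 3 to 5 mm, 2089 for over 8 mm against 3 to 5 mm and 462 against 5 to 8 mm. With slide as a random block on the 18 arrays they were 1890, 12782, 10503, 12158, 4381, 3221 and 1238 in the same order. Other pairings of the arrays, which mix replicates and so lower the spread between pairs, gave at most 7809 at 5 to 8 mm, from 3468 to 4698 over 8 mm, at most 10208 for the trend, from 362 to 2606 for 5 to 8 mm against 3 to 5 mm, and at most 1384 and 213 for over 8 mm against 3 to 5 mm and 5 to 8 mm. Each class fitted alone gave 2094 at 5 to 8 mm and 0 over 8 mm. A trended and robust prior gave 0 over 8 mm, 2433 for the trend and 0 for 5 to 8 mm against 3 to 5 mm. Asking also for a log2 fold of at least 0.58 left 2985, 1211 and 2231 at 5 to 8 mm, over 8 mm and for the trend.

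For 5 to 8 mm against 3 to 5 mm, array weights gave 119, the authors' values 59, median centring 7, no background correction 55, an offset of 16 gave 21 and plain subtraction 59. Median centring gave 6 list shifts and an estimated correlation 0. Leaving out 1 pair at a time gave 1718 to 3002 probes at 5 to 8 mm, 128 to 947 over 8 mm, 1207 to 3855 for the trend, 0 to 20 for 5 to 8 mm against 3 to 5 mm, 0 to 0 for the other counts of 0, and 1 to 8 list shifts; with fewer samples, lower counts follow in part from the construction.

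These alternatives were chosen after the data were seen. Spot medians gave 12 and a mean log2 intensity of at least 8 gave 177 for 5 to 8 mm against 3 to 5 mm. Without the pairs of the first scan batch the counts were 3 at 5 to 8 mm, 1631 for the trend and 0 for 5 to 8 mm against 3 to 5 mm. The labels give no shared replicate numbers. Pair means fell into 3 linked sets across the classes, with r from 0.320 to 0.556 within a set and at most -0.00979 between sets. Centring on the 3 pairs of a class forces part of the negative values. In each class the swapped arrays at slide areas 2, 3 and 4 belonged to sets 1, 2 and 3 in that order. For swapped arrays the sets thus follow the area given in the labels, as they do for forward arrays at 3 to 5 mm and over 8 mm. The 3 forward arrays of 5 to 8 mm all lay at area 1, so there area does not separate the sets. The labels do not say whether area stands for replicate, so the link is a hint and not a stated part of the design. A replicate block of these linked sets, chosen for their correlation and so optimistic, gave 1888 as a fixed and 1008 as a random block for 5 to 8 mm against 3 to 5 mm, 274 and 92 for over 8 mm against 3 to 5 mm, and 1 as a random block for over 8 mm against 5 to 8 mm. The block moved no other count by over 1.5 times.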

Other observations

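The tests in this part were chosen after the planned comparisons had been read. Genes were grouped by the letters that open their symbols, which gave 52 families of at least 20 measured genes, and each was tested with camera for 5 to 8 mm, over 8 mm and the trend. No family passed after Benjamini-Hochberg adjustment with either correlation setting. The smallest p for the trend belonged to the RBM genes, which encode RNA-binding proteins, with 7 of 33 higher and 1 lower (adjusted p = 0.16). The TAF genes, which encode TBP-associated factors, had 3 of 20 higher and 0 lower, and zinc finger genes named ZNF had 21 of 217 higher and 6 lower (adjusted p = 0.16 for each, and 0.659 with an estimated correlation). Genes of the AP family were lower in 7 of 23 cases and higher in 0 at 5 to 8 mm (adjusted p = 0.384).

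Calls on probes with no symbol were split by direction much as those on named ones, but were fewer. At 5 to 8 mm 1477 of 18534 probes with a symbol were higher and 1671 lower, or 46.9% of the calls higher, against 924 and 1029 of 17643, or 47.3%, without. Over 8 mm the shares were 55.0% and 54.1%, and for the trend they lay further apart, at 50.3% and 47.1%. No test was made of these shares.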
